A study of Mus musculus with 2 samples.

How the data were processed

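H3K4me1 ChIP-seq was performed on midbrain from mouse embryos of embryonic day 12.5, in 2 biological replicates of 120 and 88 pooled embryos, with chromatin fragments of 300 to 500 bp per the labels' protocols. Grouping and replicate numbers were taken from the labels, and both replicates form 1 group. The replicates come from separate pools, so the spread between them includes dissection and pooling as well as the assay.

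The authors deposited 4 peak lists in narrowPeak form on mm10, which is the GRCm38 build: the calls of each replicate, the calls made on both replicates together (the pooled call), and the subset of the pooled call kept as replicated. In the deposited lists, each peak has a fold enrichment, which is a ratio of signal to background, a p-value and a q-value given as -log10, a display score and the offset of its summit. Per the labels, the peaks of a replicate were derived from its own alignments and a further file whose kind is not stated. The aligner, the peak caller, their versions and the rule for keeping a peak as replicated are not given in the sources used here. The largest p-value in each of the 4 deposited lists was just below 0.01, so weak calls are included, and the authors' q-value was below 0.05 for 90.7% of replicate 1 peaks and 95.2% of replicate 2 peaks. Peaks called without a strict threshold and then reduced by replication depend on both libraries, so a difference in depth changes which weak regions are kept.

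No file gave read counts, so the depth is unknown and no counting interval could be set for a peak. At a fold near 5, the median -log10 p in the deposited lists was 11.7 in replicate 1, 12.3 in replicate 2 and 21.2 in the pooled call, so both replicates had similar power per peak and the pooled call more. Fold and -log10 p were used to rank and filter peaks within a list, and the log2 fold of matched peaks was compared between replicates. No columns of other samples were present.

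All chromosomes and peak ends fitted GRCm38.p6, and no summit fell on an unknown base. Genes came from GENCODE M21 (Ensembl 96) on the same build. A single replicate 1 peak off the main chromosomes was left out of position analyses, and genes on Y were left out of gene analyses. Intervals were handled with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and random placement used BEDTools 2.31.1. Coordinates are given from 1.

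Replicates were compared by overlap of at least 1 base, against 1000 circular shifts of the peaks along the part of each chromosome with known sequence (permutation, one-sided). No interval was identical in both replicates. For the fold comparison, peaks were matched 1 to 1 by largest overlap. Peak centres were assigned to promoters (within 1 kb of a protein-coding TSS), then exons, introns and intergenic sequence, against 1000 shifts (permutation, two-sided). Circular shifts keep the spacing of peaks and ignore mappability and GC content.

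Gene territories were the gene body plus 10 kb on either side, for 21728 protein-coding genes. Neighbouring territories overlap, so a peak can count for more than 1 gene, as at the Hox clusters. For each of 27 lists the median coverage was set against 10000 random lists of the same size matched on territory length in 20 bins. The permutation p (two-sided) was adjusted over the 27 lists by Benjamini-Hochberg with a threshold of 0.05, and its smallest value is 0.0002 before adjustment. Genes of a list are not independent replicates, and the p describes these regions. Peaks at most 3 kb apart were joined into domains. The words of 20 factor families were counted on both strands within 250 bp of the centres of distal peaks and in windows 5 kb to the side outside pooled peaks, beside 10 permuted words with as many CpG positions.

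The gene lists, words, tests and most alternatives were fixed before the data were examined. Named genes follow a rule fixed then too: the 3 members of each list with the highest coverage and the one with the lowest, the genes nearest the 10 strongest peaks, the genes under the 10 longest domains, and 18 genes of the midbrain, neighbouring regions and other tissues. Genes named for their difference between replicates were chosen after their values were seen, as were the members of long domains. Alternatives were leaving out each replicate (using the own calls of the other), a -log10 q of at least 5, pooled calls, other overlap rules, windows, flanks and joining distances, and other random lists. Matching on GC content, merged loci, autosomal genes, tests between lists and the log2 ratio between replicates were chosen after seeing the data. For that ratio, 0.5 percentage points were added to each coverage and random lists were matched on mean coverage in 20 bins.

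The gene-list, replicate-overlap, covered-base and word statistics were tested on simulated data first, and the others were not. With 10 percentage points added to 16 genes, 97 of 100 lists among 21728 genes were called above random at an unadjusted p below 0.05. With 5 points added 30 were, and with nothing added 1 was. The simulated values were independent between genes and unrelated to GC content, so these rates need not hold for the real lists. In simulated peak lists with 10% of peaks in common, 10.4% overlapped, against 1.01% after shifting. These 38000 peaks had equal widths and were placed at random, unlike the real peaks, so the result need not hold for them. All 20 words were recovered when planted in 10% of 20000 random windows, and 3 of 20 exceeded their permuted words with nothing planted.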

Results

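Monomethylation of lysine 4 of histone H3 (H3K4me1), a histone mark of enhancers and of the flanks of active promoters, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the mouse midbrain at embryonic day 12.5. The series has 1 group with 2 biological replicates, each a pool of embryos of both sexes from the B6NCrl strain. Replicate 1 pooled 120 embryos and replicate 2 pooled 88. The peak list of replicate 1 held 195315 peaks over 87.7 Mb and that of replicate 2 held 165486 peaks over 72.5 Mb. Calls made on both replicates together, the pooled call, held 206013 peaks, of which the authors kept 110510 as replicated. The replicated peaks had a median width of 644 bp and covered 96.0 Mb, or 3.52% of the genome (mm10). Read numbers were not given in the files, so the sequencing depth is unknown. With a single tissue, age and mark, the comparisons were replicate 1 against replicate 2 and the marked regions against the rest of the genome.

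The first comparison asked how far both pools of embryos carried the mark at the same places. Of the replicate 1 peaks, 54.7% overlapped a replicate 2 peak by at least 1 base, and 66.9% of replicate 2 peaks overlapped a replicate 1 peak. Regions with strong enrichment were nearly always marked in both pools: in the strongest 10% by the authors' fold enrichment, the shares were 95.6% and 97.6%. Among weaker peaks sharing was lower, down to 32.6% of the replicate 1 peaks with a fold between 2.38 and 2.58. When the peaks of replicate 1 were shifted along their chromosomes 1000 times, a mean of 5.44% overlapped (SD 0.209, highest 6.31%). For replicate 2 the shifted mean was 6.46% (SD 0.245, highest 7.44%). The permutation p was 0.001 for both replicates (one-sided), the smallest that 1000 shifts can give. At the level of bases, 46.4 Mb were called in both replicates, 40.8% of all bases called in either.

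Peaks found in only 1 pool were weaker and narrower than shared ones. The 88407 replicate 1 peaks without a replicate 2 partner, 45.3% of its list, had a median fold enrichment of 2.78 and a median width of 227 bp, against 3.44 and 423 bp for the partnered peaks. In replicate 2, 54833 peaks (33.1%) had no partner, with a median fold of 2.90 against 3.31. Across 94133 peaks matched between the replicates, fold enrichment was related with a Spearman rho of 0.382 and a Pearson r of 0.425 on the log2 scale. These coefficients run across peaks, which are not independent replicates. The log2 ratio of replicate 1 to replicate 2 had a median of 0.03 and an SD of 0.44, and 97.4% of matched peaks lay within 2-fold.

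**Figure D1:**
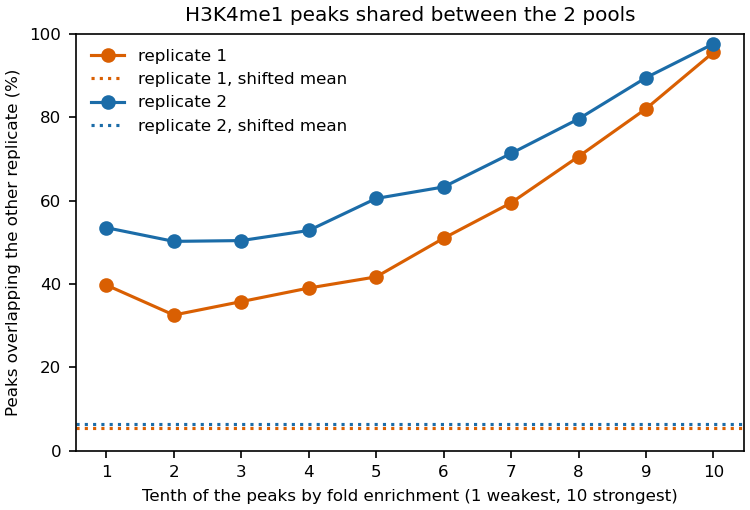
Share of the peaks of each replicate that overlapped a peak of the other by at least 1 base (vertical axis, percent), in 10 classes of equal size by fold enrichment (horizontal axis, 1 weakest to 10 strongest). Points are the 2 replicates, and dotted lines the means of 1000 shifts of all peaks of a replicate along the chromosomes (5.44% and 6.46%). Sharing reached 95.6% and 97.6% in the strongest class, and no shifts were made by class.

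The replicated list held 53.6% of the pooled-call peaks, with coordinates identical to those in the pooled call. It kept 8.58% of the weakest 10% of pooled peaks by fold, and 99.7% of those with a fold between 3.58 and 4.31. Kept peaks had a median fold of 3.28 and a median width of 644 bp, and dropped peaks 2.33 and 238 bp. Of the kept peaks, 77.4% overlapped calls of both replicates, against 0.661% of the dropped peaks. The replicated list is the set of regions used from here on.

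Promoters and introns carried the mark more often than chance placement gave, and intergenic sequence less often. Of the 110510 replicated peaks, 14.7% had their centre within 1 kb of a protein-coding transcription start site (TSS), 5.58 times the mean of shifted peaks (2.63%, SD 0.0986). Introns held 48.2% of centres, 1.32 times the shifted mean (36.4%, SD 0.65), and intergenic sequence 32.7%, 0.566 times the shifted mean (57.7%, SD 0.747). Exons outside promoters held 4.44%, 1.36 times the shifted mean. Each of these 4 permutation tests gave p = 0.002 (two-sided), the smallest that 1000 shifts allow. With promoters widened to 2.5 kb, exons no longer differed from shifted peaks (ratio 1.04, permutation p = 0.204).

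Around TSSs the mark lay on both sides of the start and less often on it. A replicated peak covered the TSS itself in 16.1% of 21728 protein-coding genes. Coverage rose to 25.5% of genes at 550 bp upstream (position -550) and to 37.5% at 1000 bp downstream. The downstream maximum was 2.32 times the value at the TSS, and the upstream maximum 1.58 times. At 5 kb, coverage was 4.72% upstream and 7.36% downstream. Both replicates showed the same shape in their own calls, with downstream maxima 2.43 (replicate 1) and 2.60 (replicate 2) times the value at the TSS.

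**Figure D2:**
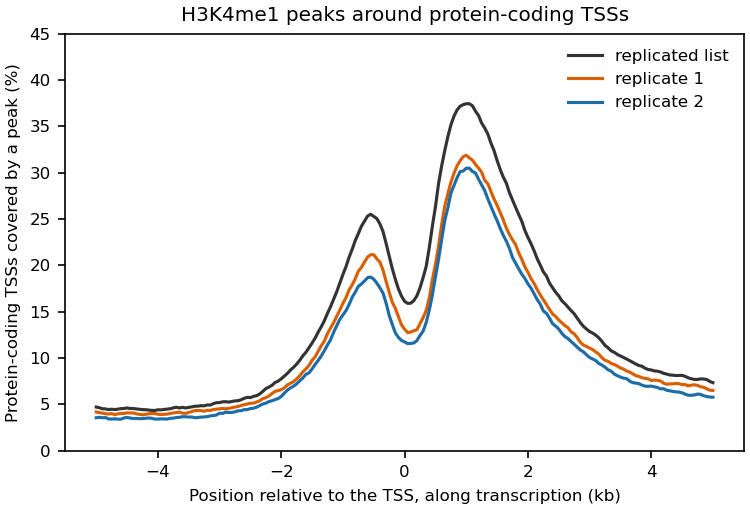
Share of 21728 protein-coding TSSs covered by an H3K4me1 peak (vertical axis, percent) at each position from 5 kb upstream to 5 kb downstream (horizontal axis, kb, negative upstream). Lines are the replicated list and the own calls of each replicate; all 3 dip at the TSS, where the replicated list covers 16.1% of genes, and are highest near 1000 bp downstream, where it covers 37.5%.

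Genes that pattern the midbrain and the isthmus, the signalling centre at its rear border, carried the mark over far more of their sequence than genes of like length. For each protein-coding gene, the territory was the gene body plus 10 kb on either side, and the value was the percent of its bases under replicated peaks. The 17 midbrain and isthmus patterning genes had a median of 25.3% (21.9 ± 1.4 in the own calls of each replicate, SD, n = 2), against 4.04% in random lists matched on territory length (adjusted permutation p = 0.0008). Random lists matched on GC content too had a median of 10.75% (adjusted permutation p = 0.0027). Where the own calls of a replicate differ from the value of a named gene with a replicated peak by over 1.5 times, the values of replicates 1 and 2 stand in parentheses, here and in the next 5 paragraphs. Of the patterning genes, 16 lay at or above the 75th percentile of genes of like length. The highest were Gbx2, a homeobox gene of the rear side of the isthmus, at 45.1%, Otx2, a homeobox gene of forebrain and midbrain, at 38.0% (24.3% and 30.5%), and En2, a homeobox gene of midbrain and cerebellum, at 35.9% (15.7% and 40.2%). Fgf8 and Wnt1, which encode secreted signals of the isthmus, stood at 29.3% and 25.3%. En1 had 18.1% (11.2% and 17.9%), Pax5 9.01% over a territory of 205.7 kb, and Pax8 the lowest value, 4.90% (5.24% and 3.21%).

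Genes of midbrain neuron types followed the same direction with different sizes. The 17 genes of GABAergic and glutamatergic fate had a median of 24.5% (adjusted permutation p = 0.0008), led by Barhl2 at 46.5% (39.3% and 27.5%), Irx3 at 41.8% (25.4% and 33.7%) and Tcf7l2 at 37.1%. Slc17a6, the vesicular glutamate transporter VGLUT2, was lowest at 5.72% (3.69% and 2.94%). The 16 ventral midbrain and dopaminergic genes had a median of 11.9% (adjusted permutation p = 0.0221; random lists 4.58%). Msx1 (31.6%; 20.8% and 23.5%), Barhl1 (28.2%) and Ddc (24.7%), which encodes the decarboxylase of dopamine synthesis, were highest in that list, and Aldh1a1 was lowest at 0.599%. Nr4a2, a nuclear receptor of dopaminergic neurons, had 24.5% (21.8% and 15.3%), Th, tyrosine hydroxylase, 11.0% (11.8% and 3.96%), Lmx1a 8.43% and Foxa2 5.45% (5.37% and 2.46%). The call for the ventral list ended with replicate 2 calls alone (adjusted permutation p = 0.0564), with 50 kb flanks (0.351) and with random lists matched on GC content too (0.121).

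Neural progenitor and neurogenesis genes had the widest coverage of the 27 lists in the replicated list; in replicate 2 calls alone, progenitor genes (20.7%) stood below midbrain and isthmus patterning genes (22.9%). The 18 progenitor genes had a median of 36.5%, 27.5 ± 9.67 in the own calls of each replicate (SD, n = 2; replicate 1 34.4%, replicate 2 20.7%). Sox2 stood at 62.3%, Sox1 at 58.8% and Nes, the intermediate filament nestin, at 56.9%, while Prom1 had 3.97% (3.57% and 2.19%). The 15 neurogenesis genes had a median of 37.9% (31.3 ± 1.27, SD, n = 2), with Btg2 at 62.3%, the proneural factors Neurog2 at 53.9% (51.4% and 34.2%) and Ascl1 at 52.9%, and Neurod4 lowest at 5.25%. Random lists had medians of 4.78% and 5.25%, and both adjusted permutation p-values were 0.0008, the smallest these lists reached. With GC content matched too, the random medians were 8.10% and 8.71% (adjusted permutation p = 0.0013 for both). Pan-neuronal genes had a lower median, 9.74% (adjusted permutation p = 0.0194), with Elavl3 at 24.4%, Tubb3 at 24.3% and Rbfox3 at 19.8%. That call ended with replicate 1 calls alone (adjusted permutation p = 0.104), with 50 kb flanks (0.138) and with random lists not matched on length (0.0910).

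Signalling and guidance genes lay above random lists as well. Morphogen signalling genes (20) had a median of 20.9% and axon guidance genes (20) one of 13.0%, both with adjusted permutation p = 0.0008. Jag1, a Notch ligand, had 46.7%, Axin2, a target of Wnt signalling, 46.0%, and Ptch1, the Hedgehog receptor, 42.3%. Efna2 had 60.5% (39.7% and 60.4%), Sema3f 39.6% and the X-linked Efnb1 37.7% (35.4% and 21.4%), against 1.11% for Sema3a (1.65% and 0.479%). Glial genes (12) had a median of 14.5% (adjusted permutation p = 0.0162), led by Olig2 at 49.9% (44.0% and 20.3%), Sox10 at 22.4% (18.9% and 13.4%) and Mbp at 21.9%, while Plp1 had no replicated peak. Neural crest and cranial ganglion genes (12) had a median of 14.5% (adjusted permutation p = 0.0378), with Prdm12 at 25.0% (15.5% and 22.0%), Ntrk1 at 22.7% and Ngfr at 18.7% (17.9% and 11.0%). Both of these calls ended with replicate 2 calls alone (adjusted permutation p = 0.103 for glia, 0.180 for neural crest) and with GC-matched random lists (0.0806 and 0.121). The neural crest call was lost in 5 of 11 alternatives, ending also at a -log10 q of at least 5 (0.0508), with 50 kb flanks (0.714) and with 5 kb around the TSS (0.0679).

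Genes of the neighbouring brain regions gave unlike values. Forebrain genes (17) had a median of 15.4% (14.0 ± 5.17, SD, n = 2), above random lists (5.15%, adjusted permutation p = 0.0194). Emx2 reached 47.8% (43.5% and 28.2%), Lhx2 38.1% (39.6% and 20.2%) and Six3 31.9% (38.4% and 13.1%). Foxg1, a transcription factor of the telencephalon, had 5.22% in the replicated list and more in the own calls of either replicate (11.0% and 9.09%), and Satb2 had 4.81%. The forebrain call ended with replicate 2 calls alone (adjusted permutation p = 0.0545) and with 50 kb flanks (0.246). Hindbrain and anterior Hox genes (18) had a median of 8.73% (adjusted permutation p = 0.338), with Mafb at 29.3% (23.1% and 18.3%), Egr2 at 24.3%, Atoh1 at 17.3% (10.2% and 12.8%) and no replicated peak at Hoxb1. Posterior Hox genes (16) had a median of 6.40% (adjusted permutation p = 0.898), and Hoxa9 stood at 9.45% (7.49% and 6.20%). With GC-matched random lists, posterior Hox genes were called below random (adjusted permutation p = 0.0472). The difference between lists was tested by permuting genes between them, a test chosen after seeing the data. Among genes of like territory length, the 50 genes of the 3 midbrain lists had a median percentile of 92.6. This was above posterior Hox genes (52.0, adjusted permutation p = 2.5e-05), hindbrain and anterior Hox genes (61.7, adjusted permutation p = 0.00018) and forebrain genes (81.6, adjusted permutation p = 0.034). Heart muscle genes, tested alongside, stood at 68.4 (adjusted permutation p = 0.0023). These tests were not repeated in each replicate, with GC matching or with merged loci. Forebrain genes had a median coverage of 17.7% in replicate 1 and 10.4% in replicate 2, and genes of a Hox cluster share territory.

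Genes of tissues outside the nervous system mostly lay within the range of random lists. None of the 11 lists for endothelium, mesenchyme, macrophages, erythroid cells, lymphoid cells, liver, heart muscle, skeletal muscle, gut, epidermis and germ cells passed the threshold against length-matched lists. Mesenchyme and pericyte genes were called above random with peak centres assigned to the nearest TSS (adjusted permutation p = 0.0045) and with GC-matched lists (0.0472), and epidermis genes below random with GC-matched lists (0.0432). The medians of the 11 lists ran from 0% for 13 erythroid genes to 8.04% for 14 skeletal muscle genes. Single members reached values like those of neural genes: the highest were Grhl3 of epidermis at 28.0%, Nanos3 of germ cells at 25.3%, Tnni3 of heart muscle at 24.4%, Sox18 of endothelium at 23.7%, Twist1 of mesenchyme at 23.1% and Klf1 of erythroid cells at 22.1%. In the other lists the highest were Pygm of skeletal muscle at 19.5% (16.9% and 12.7%), Cd4 of lymphoid cells at 18.5%, C1qa of macrophages at 17.8% (12.2% and 11.8%), Cdx1 of gut at 15.5% (9.25% and 13.4%) and Apoh of liver at 8.13%. Alb, serum albumin, Gata1, a factor of red cell development, Il7r, Itgam and Rhag had no replicated peak in their territories, and Myod1, a factor of muscle development, had 10.97% (8.64% and 5.94%). Against the 152 genes of these lists, the midbrain genes were 46.5 percentile points higher (adjusted permutation p = 2.5e-05). Housekeeping genes (14) had a median of 12.8% and missed the threshold (adjusted permutation p = 0.0594), with Actb at 32.4% and the X-linked Hprt at 0. They passed it above random in 5 of 11 alternatives: replicate 2 calls alone (0.0462), 5 kb around the TSS (0.0328), random lists not matched on length (0.0261), GC-matched lists (0.0472) and autosomal genes (0.0279). Cell cycle genes (15) had a median of 9.09% (adjusted permutation p = 0.299), and passed only with 5 kb around the TSS (0.0150). Olfactory receptor genes, which are expressed in the nasal epithelium, had no replicated peak in 1084 of 1134 territories (adjusted permutation p = 0.0008, below random lists). With GC-matched random lists this last call ended, but that test could not decide. The random median fell from 4.48% to 0, equal to the median of these genes, and coverage cannot lie below 0. Genes are not independent replicates in any of these tests.

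**Figure D3:**
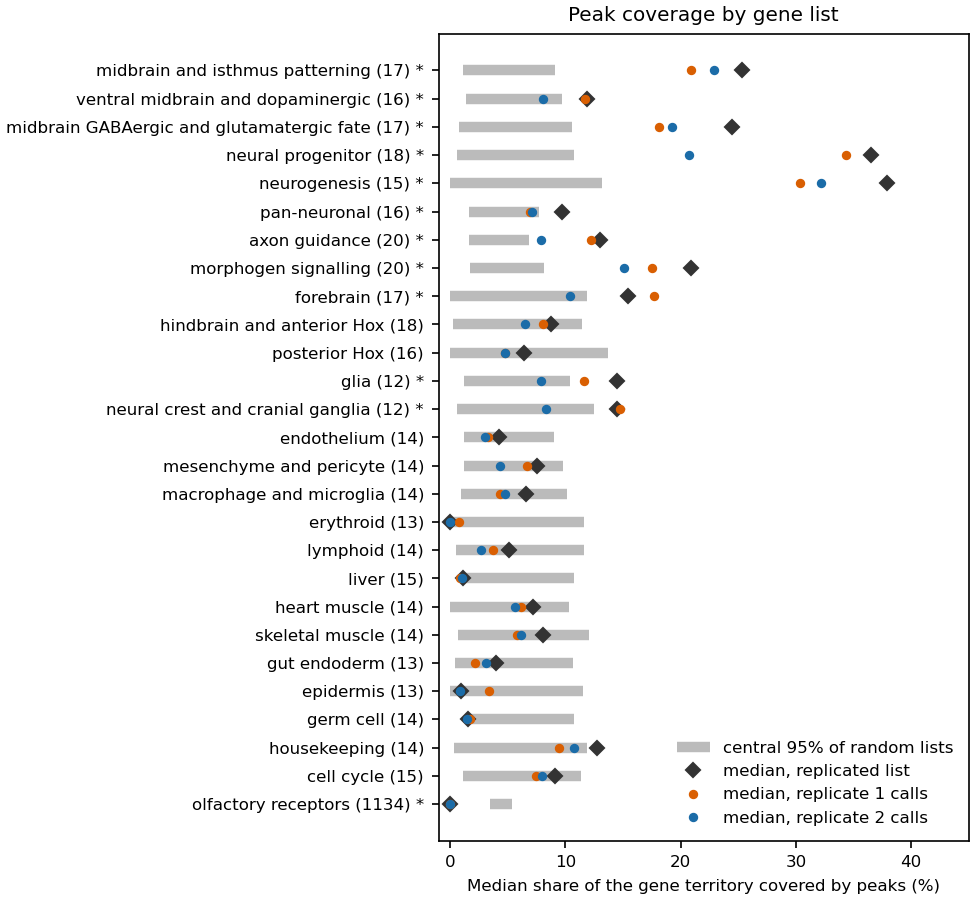
Median share of the gene territory covered by peaks (horizontal axis, percent) for 27 gene lists (vertical axis, genes measured in parentheses, asterisk for an adjusted p below 0.05). Diamonds are the replicated list, orange and blue points the own calls of replicates 1 and 2, and grey bars the central 95% of random lists matched on territory length; neurogenesis (37.9%) and neural progenitor genes (36.5%) lie farthest right.

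The 2 pools differed at genes of particular brain regions and of some other lists. Forebrain genes were covered more in replicate 1: the log2 ratio of coverage, replicate 1 over replicate 2 with 0.5 percentage points added to each, had a median of 0.63 over the 17 genes. Random lists matched on mean coverage had a median of 0.13, and the forebrain list lay at their 100th percentile. Fezf2 was covered over 40.3% in replicate 1 and 9.65% in replicate 2, Dlx1 over 36.1% and 8.91%, and Six3 over 38.4% and 13.1%. Midbrain and isthmus patterning genes went the other way, with a median log2 ratio of -0.20 at percentile 0. En2 was covered over 15.7% in replicate 1 and 40.2% in replicate 2, Pax7, a factor of the dorsal midbrain, over 22.1% and 34.8%, Pax3 over 8.85% and 22.6%, and Dmbx1 over 11.0% and 22.9%. Forebrain territories held 248 peak centres in replicate 1 and 154 in replicate 2, and midbrain and isthmus territories 390 and 456. The fold at peaks called in both replicates showed no such difference: the median log2 ratio was 0.03 at 91 forebrain peaks and 0.03 at 217 midbrain and isthmus peaks, as over all matched peaks. Peaks called in 1 replicate only have no place in that ratio.

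Among all genes with a mean coverage of at least 10%, En2 had the largest excess in replicate 2, followed by Efna2 (39.7% and 60.4%), Irx2 (21.9% and 41.9%) and Irx1 (17.7% and 36.4%). Fezf2 had the largest excess in replicate 1 (30.7 percentage points), followed by Pax6 (29.5 points), a homeobox gene of forebrain and eye, and Gsx2 (28.3 points). Neural progenitor genes (percentile 99.98) and neural crest and cranial ganglion genes (percentile 100) also leaned to replicate 1. Neural crest genes did so by more than forebrain genes (median log2 ratio 0.69). Gut endoderm genes leaned to replicate 2 by slightly more than midbrain and isthmus patterning genes (-0.22). Hindbrain and anterior Hox genes (percentile 63.5), posterior Hox genes (percentile 49.1) and the cell cycle list (percentile 37.9) lay inside their random lists. There is 1 library on each side, so these percentiles describe the 2 libraries and are not tests. This measure was chosen after seeing the data; in the planned one, the forebrain list lay at percentile 100 in replicate 1 and 99.0 in replicate 2 among length-matched lists.

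**Figure D4:**
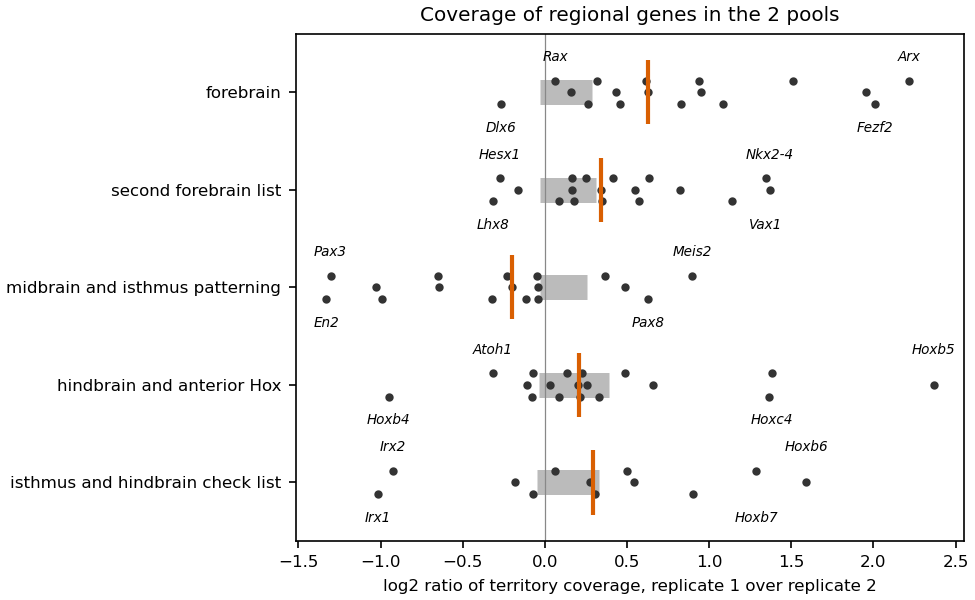
Log2 ratio of territory coverage, replicate 1 over replicate 2 (horizontal axis), for the genes of 5 lists of brain regions (vertical axis). Points are genes, orange bars list medians and grey bars the central 95% of random lists matched on mean coverage; the forebrain median (0.63) lies right of its bar and the midbrain and isthmus median (-0.20) left of it.

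**Figure D5:**
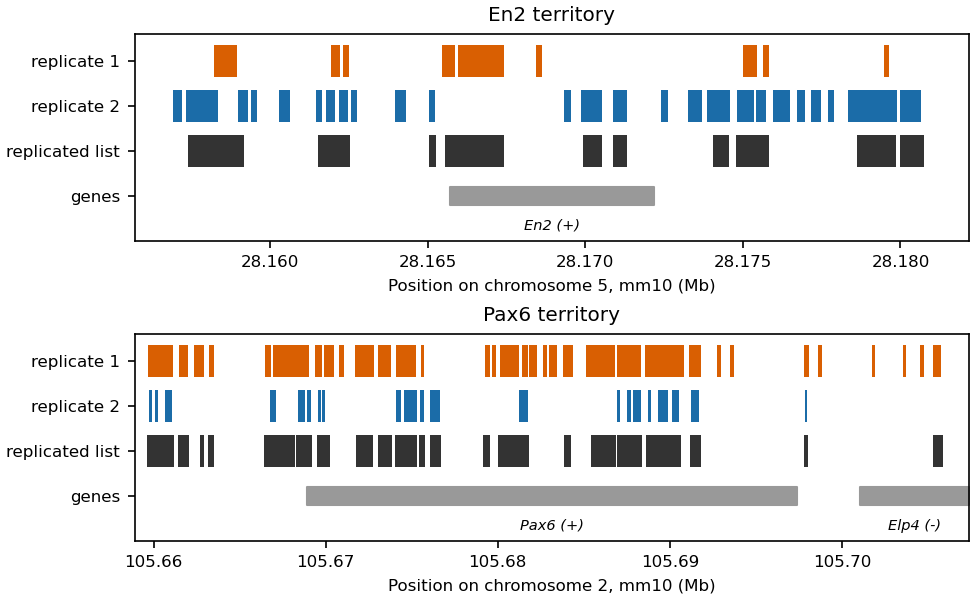
Peaks in the territories of En2 (chromosome 5, 28155694 to 28182166) and Pax6 (chromosome 2, 105658900 to 105707364), with position in Mb on mm10 on the horizontal axis and rows for replicate 1, replicate 2, the replicated list and protein-coding genes. Replicate 1 has 9 peaks at En2 and 33 at Pax6, and replicate 2 has 25 and 21.

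The longest marked stretches lay over Ephb2, Msi2 and Ssbp3. Replicated peaks at most 3 kb apart were joined into 58492 domains with a median length of 1159 bp, of which 348 reached 20 kb and 17 reached 50 kb. The longest was 120.5 kb over Ephb2, an Eph receptor (chromosome 4, 136720715 to 136841222), and 78.9% of its bases lay under replicated peaks (64.2% and 64.1% in the own calls of replicates 1 and 2). The next were 117.9 kb over Msi2, an RNA-binding protein of stem and progenitor cells (chromosome 11, 88496603 to 88614537), and 100.6 kb over Ssbp3 (chromosome 4, 106905091 to 107005732). Further domains among the 10 longest lay over Gse1 with 83.4 kb and 65.0 kb, Macrod1 and Otub1 with 76.6 kb, Tcf20 with 73.6 kb, Ccdc85c with 70.5 kb and Sema6a with 68.3 kb. A domain of 65.2 kb on chromosome 7 overlapped no protein-coding gene and had Polg as its nearest TSS. Among neural progenitor genes, 5 of 18 (Hes5, Pax6, Notch1, Nr2e1 and Zic2) were overlapped by a domain of at least 20 kb, against 1.62% of all protein-coding genes. So were 3 of 17 midbrain patterning genes (En2, Otx2 and Pax7) and 0 of 16 ventral midbrain genes. The progenitor share was the highest of the lists, and these shares were not matched on territory length. Coverage in replicates 1 and 2 was uneven at Pax6 (44.2% and 14.7%), Zic2 (40.3% and 15.9%) and, the other way, En2 (15.7% and 40.2%).

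The peaks with the highest fold enrichment were wide, and their centres lay mostly in introns. Introns and promoters named in this paragraph are those of peak centres, and a wide peak can reach beyond them. The highest, with a fold of 11.8, was 12895 bp wide (chromosome 11, 98959084 to 98971978). Its centre lay in an intron of Rara, a retinoic acid receptor, 5.12 kb from the nearest TSS, and the peak reached past that TSS. Gse1 introns held 2 of the 9 highest (folds 11.5 and 10.5). Bcl9l, a cofactor of beta-catenin, and Kcnh2, a potassium channel, had theirs at the promoter (folds 11.0 and 10.9). Introns of Ahdc1 (10.8), Ncor2, a nuclear receptor corepressor (10.5), Ccdc85c (10.2) and Col2a1, type II collagen (10.1, level with peaks at Gm43738, Zfp423 and a further Gse1 intron), held others, and an intron of Ssbp4 held a peak of 10.3 with Isyna1 as its nearest TSS. The 1000 highest peaks lay a median of 3.12 kb from a TSS, against 20.2 kb for all replicated peaks, and 60.2% of them were intronic against 48.2%. In replicate 1 calls alone the 1000 highest lay at 6.84 kb and in replicate 2 calls alone at 3.83 kb.

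Of 20 words bound by transcription factor families, 7 were more frequent at distal peaks, relative to the sequence beside them, than all their permuted words, and words of neural factors lay on both sides of that line. In 84655 windows of 250 bp either side of the centres of peaks more than 1 kb from a TSS, the E-box CAGCTG, bound by proneural basic helix-loop-helix factors, occurred in 32.7%, against 20.2% of windows 5 kb to the side. The ratio was 1.62, and the highest ratio among 10 words with the same columns in another order was 1.52. The RFX word had a ratio of 1.54 (3.91% against 2.54%; highest permuted 1.20), and the homeodomain word TAATTA one of 1.08 (14.8% against 13.7%; highest permuted 0.915). The CTCF core (2.23), TEAD (1.11), MEF2 (1.07) and HNF1 (0.906) words also lay above all their permuted words, HNF1 on 29 and 32 windows only. The POU octamer had a ratio of 1.47 with a highest permuted ratio of 1.47, the SOX word 1.12 with 1.20, and the E-box CATCTG 1.07 with 1.18. The OTX word, less frequent in peaks than beside them (0.914), also lay within its permuted words. CAGCTG, RFX, TAATTA and TEAD kept their place under all 5 alternatives. The CTCF core lay within its permuted words at a -log10 q of at least 5 (2.15, highest permuted 2.19) and below all of them with 100 bp either side (1.52, lowest permuted 1.57). With 100 bp either side, MEF2 (0.899) and HNF1 (0.714) lay within theirs. POU exceeded its permuted words in 3 of the 5 alternatives and the forkhead word in 4. Peak windows had a GC content of 48.2% and side windows 44.2%. In random sequence with nothing planted, 3 of 20 words exceeded all their permuted words. That sequence had the same base composition in peak and side windows, unlike here. The 3 of 20 is therefore no reference for the 7 of 20, and these ratios carry no test.

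The X chromosome held far fewer peaks than any autosome. It had 4.64 replicated peaks per Mb, while the autosomes ranged from 35.4 on chromosome 14 to 67.0 on chromosome 11. The ratio of X to the median autosome was 0.105, and 0.127 and 0.0984 in the own calls of replicates 1 and 2. A replicated peak centre lay in the territory of 30.4% of 948 X-linked genes and of 77.6% of 20780 autosomal genes. Efnb1, with 9 peaks in its territory (35.4% and 21.4% covered in replicates 1 and 2), was among the X-linked genes with wide coverage, while Dcx, a marker of young neurons, had 1.59% and Gata1, Hprt and Plp1 had no replicated peak. The median fold of X-linked peaks was 2.98 and that of autosomes ran from 3.23 to 3.38. No peak in any of the 4 lists lay on the Y chromosome.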

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

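Among the alternatives, matching on GC content, merged loci and autosomal genes were chosen after seeing the data; the others were planned. No call against random lists turned to the other side. Posterior Hox genes, not called at percentile 60.1, were called below random at percentile 1.04 with GC matching, and heart muscle genes, called in neither, went from 86.4 to 13.5. The CTCF core went from above all its permuted words to below them with 100 bp either side (ratio 1.52), and 5 other words (MEF2, HNF1, POU, forkhead and ETS) moved past or back within their permuted words under some alternative. The overlap of replicates stayed past its threshold under all 5 alternatives, between 42.5% and 59.0% for replicate 1 and between 55.8% and 66.9% for replicate 2, and promoter, intron and intergenic shares stayed past theirs under all 6. For the overlap, merging overlapping calls left every count the same and so was no further check. Random placement changed only the comparison, with 20 draws (permutation p = 0.0476, one-sided, the smallest they allow). Requiring a peak to be covered over at least 50% of its bases raised unmatched peaks to 57.5% (replicate 1) and 44.2% (replicate 2), by the construction of a stricter rule. The rho of fold between replicates was 0.481 for reciprocal overlaps of at least 50% and 0.461 for -log10 p. The replicated list kept 100% of the strongest 10% when ranked by -log10 p, as by fold to the digits shown. The exon share fell to 1.04 times shifted peaks with 2.5 kb promoters. The downstream maximum over the TSS value ran from 2.43 to 2.60 without each replicate and was 2.48 at a -log10 q of at least 5. With 50 kb flanks 7 lists lay above random lists instead of 11, and with GC matching 2 lay below (posterior Hox and epidermis) instead of 1. Domains of at least 20 kb numbered 741 in pooled calls and 4457 with 12.5 kb joining, against 348. The median TSS distance of the strongest peaks ran from 3.83 to 6.84 kb without each replicate, and the X to autosome ratio from 0.0984 to 0.127. Where no construction is named, the cause was not tested. Lists for midbrain patterning, GABAergic and glutamatergic fate, progenitors, neurogenesis, axon guidance and morphogen signalling kept their calls under all 11 alternatives. No paired analysis was possible because the series has 1 group. Weak peaks limit the comparison: sharing between replicates was 32.6% for replicate 1 peaks with a fold between 2.38 and 2.58, and depth could not be set beside it.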

Other observations

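Of the tests here, that of the forebrain list against random lists, those with GC matching and those of X peaks at a fold lower by 1.5 times or at a threshold other than 3 were chosen after the result was seen; the others were written down first. Beyond the regional lists, the genes with the largest excess in replicate 2 included Foxb1 (36.6% in replicate 1, 52.2% in replicate 2), Sox13 (22.6% and 37.5%), Tal2, a factor of midbrain GABAergic neurons (15.2% and 28.8%), Prox1 (20.0% and 30.8%) and Foxn4 (16.3% and 26.9%). Those with the largest excess in replicate 1 included Zic2 (40.3% and 15.9%), Foxo6 (51.9% and 27.5%), Olig2 (44.0% and 20.3%), Hmga2 (33.6% and 12.8%), Nfix (46.9% and 26.4%), Gbx1 (23.4% and 4.64%) and Bcl11b (52.8% and 35.4%). Gut endoderm genes (percentile 0.35) and skeletal muscle genes (percentile 1.53) leaned to replicate 2 among 28 lists, at median coverages of only 3.13% and 6.19% there.

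The regional difference between the pools might come from the larger number of calls in replicate 1, but random lists of like mean coverage hold that number and the forebrain list still lay at percentile 100. A candidate explanation is that the replicate 1 pool held more tissue from in front of the midbrain. It rests on coverage alone. The median log2 ratio of fold at peaks called in both replicates was 0.03 at 91 forebrain peaks and over all matched peaks. A second list of 18 forebrain, eye and hypothalamus genes, none of them in the first, lay at percentile 98.81, with Vax1 (25.0% and 9.53%), Nkx2-4 (10.2% and 3.67%) and Gsx2 (51.4% and 23.1%) leading and Lhx8, Hesx1 and Foxd1 going the other way. For tissue from behind the midbrain in replicate 2, a list of 12 genes drawn up for isthmus and hindbrain lay at percentile 95.09, towards replicate 1. By the criterion written down beforehand, this value counted against that explanation. The list still cannot decide the question, since its members disagree and some share territory. The neighbouring Hoxb6, Hoxb7 and Hoxb8 leaned to replicate 1 (log2 ratios 1.59, 1.29 and 0.308). Irx1 and Irx2 leaned to replicate 2 (-1.01 and -0.924). Other developmental lists leaned both ways, neural progenitor, neural crest and morphogen signalling genes (percentiles 99.98, 100 and 99.41) to replicate 1 and midbrain patterning genes (percentile 0) to replicate 2, and dissection, age and pooling cannot be separated with 1 library each.

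The height of the neural lists might follow from GC-rich territories, since coverage and GC content were related across genes with a rho of 0.692. With GC-rich territories matched, 8 of the 11 lists above random kept their call, midbrain patterning (25.3% against a random median of 10.7%, before 4.04%) and neurogenesis (37.9% against 8.71%, before 5.25%) among them, which argues against GC content as the whole cause for these 8. For the 3 lists that lost the call, GC-rich territories stay open: the random median rose from 4.58% to 7.42% for ventral midbrain genes (median 11.9%), from 4.62% to 7.59% for glia (14.5%) and from 5.44% to 8.60% for neural crest (14.5%). Their calls ended because the random lists rose while the lists' own medians stood still, and they remained above the random medians. Tissue identity, which the labels name, stays a hypothesis for the other 8 and was not tested. Forebrain genes are among these 8.

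The scarcity of peaks on X was set against 3 explanations. Fewer genes on X could not account for it, as X had 0.822 replicated peaks per protein-coding gene and the lowest autosome, chromosome 7, had 3.29. AT-rich sequence failed the criterion written down for it beforehand. With autosomal 10 kb windows weighted to the GC content of X, X had 0.250 of the autosomal share of windows with a peak centre. Unweighted it had 0.133. A peak centre lay in 3.35% of X windows, against 25.1% of autosomal windows unweighted and 13.4% weighted. GC content thus went with a sizeable part of the gap, and X stayed well below autosomal windows of like GC content. A lower dose of X, with 1 copy in males and 1 inactive copy in females, may account for it as a halved fold, since X peaks with a fold of at least 3 were 1.44 times as dense as those of the median autosome at a fold of at least 6; at a threshold of 2.5 X lay just below the median autosome (4.09 against 4.20 per Mb) and at 2 below the lowest (4.62 against 8.02), where few weak peaks were kept as replicated (14.2% of pooled peaks with a fold between 2.29 and 2.39). At 3.5 X had 0.846 peaks per Mb, against 0.477 on the median autosome at a fold of 7 (highest 1.13). At 4 it had 0.292, against 0.109 at a fold of 8 (highest 0.362). A fold lower by 1.5 times was not enough at thresholds of 3, 3.5 and 4 (2.21 peaks per Mb on X at 3, lowest autosome 4.58 at 4.5). A halved fold thus did not describe X alike at all thresholds, and the rule asked only that X be no less dense. Dose stays open for the stronger peaks, beside how the background was set, which was not tested.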
